A study of Homo sapiens and Macaca fascicularis and Mus musculus with 74 samples.

How the data were processed

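SC3-seq, a sequencing method that reads the 3' ends of transcripts, was applied by the authors to 37 human libraries, 10 mouse libraries and 27 cynomolgus monkey single cells on a SOLiD 5500XL sequencer. Human libraries came from 1 ng of RNA and mouse libraries from 10 ng, except the mouse day 2 libraries, from 1 ng. The human libraries were hiPSCs, iMeLCs made with Activin A and CHIR99021, and germ cell-like cells made with BMP4, LIF, SCF and EGF, sorted on a PRDM1 (BT) and a TFAP2C (AG) reporter or, in line 585A1, on the surface markers EpCAM and CD49f (CSM+). The mouse libraries were mESCs, EpiLCs and cells sorted on Blimp1 (BV) and stella (SC) reporters. The cynomolgus cells were cyESCs and germ cells from dissociated embryonic genital ridges.

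The deposited values are a normalized signal per gene, which the authors gave as reads-per-million values (RPM) with no correction for transcript length. Gene values summed to 999813 to 999963 per library and 999835 to 999999 per cell, and 92 spike-in controls stood on the same scale on top of that sum. The submitters' notes name cutadapt 1.3, TopHat 1.4.1 and Cufflinks 2.2.0 and the builds hg19 and mm10; they state no build for cynomolgus and no filter. The files held values for 24869 human, 26219 mouse and 28797 cynomolgus genes.

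The values stepped in whole reads, which gave the depth of each library. Within a tolerance of 0.02 reads, 98.6% to 99.4% of values up to 200 reads in human, 99.4% to 99.8% in mouse and 99.7% to 99.9% in cynomolgus were whole. The first series of 585B1-868 had 3.21 to 4.65 M (mega) gene reads in replicate 1 and 0.641 to 0.747 M reads in replicate 2, so replicate number and depth go together there. The other 25 human libraries had 2.36 to 8.08 M reads. Mouse libraries had 0.668 to 1.04 M reads, and up to 8.30 M reads at day 2. Cells had 1.68 to 3.28 M reads (cyESC), 1.35 to 4.61 (E43), 0.642 to 1.62 (E50) and 1.11 to 2.71 (E51). Correlations between replicates, across genes, were 0.934 to 0.946 in the first series, 0.977 to 0.983 in the star set and 585A1, 0.957 to 0.971 in the genotype set and 0.934 to 0.972 in mouse.

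Groups were taken from the labels, and all tests were two-sided. Changes were tested with limma 3.58.1 in R 4.3.3 on log2 of RPM plus 1, for genes with at least 10 RPM in at least 2 libraries, with a mean per group, and with eBayes using a trend and robust fitting. There were 3 fits: 22 libraries of 585B1-868 and 585A1 (10775 genes), 15 of the genotype set (10690 genes) and 10 of mouse (10041 genes). Calls needed a Benjamini-Hochberg adjusted p under 0.05 and an absolute log2 change of at least 1, in 20 comparisons, of which 3 were differences between changes. In all, 21 gene lists were tested with camera at a correlation of 0.01, and with an estimated correlation, where at least 5 genes were tested. Genes were also adjusted over each list alone. Lists, comparisons and thresholds were fixed before the data were examined.

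Cynomolgus cells were compared without a test, with each age set beside cyESCs. A list's median ratio was ranked among 10000 random lists, each gene replaced by 1 of the 100 nearest genes on either side in mean level, over 10412 genes kept. Folds against groups with no read used a floor of 3 reads over the group, and ratios with 1 to 3 reads have 95% intervals. In human and mouse both pooled the reads of a group over its libraries. Reads are not independent molecules, so floors and intervals cover counting error only.

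Genes were named by rule: the 8 largest rises and 8 largest falls past both thresholds in main comparisons and the 3 largest each way in others. In cynomolgus they were the 10 largest ratios each way among genes with a mean of at least 10 RPM, changed the same way at all 3 ages and detected in at least 50% of the cells on the higher side. Members of the gene lists were also named, with 2 to 4 examples of the largest changes per list, and PRDM1 and TFAP2C throughout the genotype set. Symbols of uncharacterized loci, small RNAs and long intergenic RNAs were passed over, as were XIST and genes annotated on the Y chromosome. In cynomolgus this left out 3103 of the 10412 genes kept.

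The test was tested on reads simulated at the depth of each library, with changes of log2 1.5, 2 and 3 placed in 200 genes of 1 comparison per fit. The simulated spread between libraries was set at a dispersion of 0.03 for every gene and was not taken from the data. Alternatives were no filter, a filter at 30, pseudocounts of 0.1 and 10, trimmed-mean scaling, quantile normalization, a replicate block, all human libraries in a single fit, and leaving out each library in turn, where the lone library left was assumed to vary like the other groups. Without shallow libraries each group of the first series held 1 library, and all of its spread came from the star set and 585A1, whose replicates agreed better. Library weights, leaving out shallow libraries, leaving out the mouse day 2 libraries, and a crossed pairing of the genotype lines were added after the data were seen. Line stems in the labels pair the wt and ko lines. The correlation of residuals by stem was checked between all wt and ko groups at all stages, from -0.2 to 0.146 with a median of 0.0225. Between wt and ko at the same stage it was -0.02 in iPSCs, -0.2 at day 2 and 0.0834 at day 4. The libraries of the het line, 1 per stage, were not compared in a test. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.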

Results

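Levels are the deposited reads-per-million values over gene reads (RPM), given as mean ± SD over the 2 libraries of a group (n = 2) unless another n is named. A gene was called when its limma adjusted p was under 0.05 and its change was at least 1 on the log2 scale, and "rose" or "fell" is used for called genes alone. Where a group held no read of a gene, the fold is a bound against 3 reads over that group, and where it held 1 to 3 reads the ratio has a 95% counting interval. In human and mouse these bounds and ratios pool the reads of a group over its libraries, so deeper libraries weigh more. They can therefore lie well above or below the ratio of the mean levels printed beside them. Nothing in the labels says that the 2 libraries of a group were separate cultures, so outside the genotype set the spread behind the tests can be technical. Cells sorted on reporters of PRDM1 and TFAP2C, or in mouse of Blimp1 and stella, were selected for those genes. Rises of those genes, and their part in the early germ cell list, are therefore not independent of the sort.

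Incipient mesoderm-like cells (iMeLCs), made from human induced pluripotent stem cells (hiPSCs) of line 585B1-868 with Activin A and a WNT agonist, carried primitive streak transcripts that hiPSCs hardly held. LEFTY2, a NODAL antagonist, rose from 2.00 ± 2.83 to 1131 ± 74.8 RPM (log2 change 8.98, SE 0.56, adjusted p = 1.12e-07). LEFTY1 rose from 13.9 ± 0.842 to 1168 ± 44.6 RPM and NODAL itself from 3.84 ± 2.91 to 268 ± 41.8 RPM. The mesendoderm regulator EOMES reached 88.2 ± 16.8 RPM against 1 read in hiPSCs (ratio 495, interval 88.3 to 19600), and MIXL1 reached 83.1 ± 19.1 against 0.445 ± 0.629 RPM. SP5, a WNT target, went from 0 reads to 147 ± 17.2 RPM, at least 241-fold higher. The T-box factor T (brachyury; hg19 chromosome 6, 166571144 to 166582188) went from 0 reads to 39.8 ± 14.7 RPM, at least 79.9-fold higher. GAD1, a glutamate decarboxylase, and the protease TMPRSS11E completed the 8 largest rises, at 67.8 ± 0.662 and 78.4 ± 1.09 RPM.

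In the same step the WNT antagonist SFRP1 fell from 1133 ± 313 to 103 ± 12.2 RPM and the synaptic protein gene NPTX1 from 143 ± 96.2 to 2.07 ± 1.04 RPM. CUZD1, SOHLH2, CLC, RASGRP2, SHISA2 and ABCA1 made up the rest of the 8 largest falls. The pluripotency factor NANOG rose from 95.2 ± 28.3 to 271 ± 50.3 RPM, and SOX2 was not called at 277 ± 14.1 and 191 ± 3.17 RPM. In all, 467 of 10775 genes were called, 276 higher and 191 lower. On simulated reads 12.8% of the calls in this comparison were false, over the 5% set. Of 12 primitive streak genes tested 8 rose, and adjusted over the list alone 8 rose and 1 fell (camera adjusted p = 6.50e-21, and 0.00014 with an estimated correlation). Of 6 WNT targets RNF43, TCF7 and AXIN2 rose, 4 adjusted over the list alone (adjusted p = 2.37e-05, and 0.0408 with an estimated correlation). Of 16 early germ cell genes TFAP2C, PDPN and SOX15 rose, 5 adjusted over the list alone. That list's test depended on the processing: it did not pass in the main fit (adjusted p = 0.0573) and passed with a replicate block (0.03145), library weights (0.0474) and quantile normalization (0.0445).

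At day 2 of culture with BMP4, SCF, EGF and LIF, cells positive for both the BLIMP1 (PRDM1) and TFAP2C reporters (BTAG+) held the main germ cell regulators. SOX17 (hg19 chromosome 8, 55370495 to 55373452), an endoderm and germ cell factor, went from 0 reads in iMeLCs to 608 ± 334 RPM, at least 567-fold higher. PRDM1 (chromosome 6, 106441338 to 106557814), the repressor BLIMP1, rose from 2.70 ± 1.92 to 198 ± 10.2 RPM. TFAP2C (chromosome 20, 55204362 to 55214339) rose from 19.1 ± 7.12 to 471 ± 135 RPM. The sort used reporters of PRDM1 and TFAP2C, so the rises of those genes were partly selected by the gate. The RNA-binding factor NANOS3 (chromosome 19, 13972877 to 13991571) went from 0 reads to 54.5 ± 10.8 RPM, at least 79.4-fold higher. CXCR4, a migration receptor, rose from 1.92 ± 0.817 to 431 ± 95.4 RPM (log2 change 7.22, SE 0.35, adjusted p = 4.69e-12).

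HAPLN1, PCP4L1, NRK, CRHBP, IFI16 and FAM20A were the other large rises at day 2, IFI16 going from 1.60 ± 0.376 to 265 ± 23.2 RPM. SOX2 fell from 191 ± 3.17 to 1.83 ± 2.58 RPM (log2 change -6.47, SE 0.54), ZIC2 from 191 ± 4.59 to 2.79 ± 3.95 RPM and EOMES from 88.2 ± 16.8 to 1.18 ± 1.67 RPM. GLIPR1L1, VAT1L, BCAT1, CD44 and GFPT2 were the other large falls. Of 10775 genes 2328 were called, 1437 higher and 891 lower. Early germ cell genes rose in 11 of 16 cases, also adjusted over the list alone (camera adjusted p = 1.08e-11, and 0.000148 with an estimated correlation). BMP targets rose in 9 of 11 cases, also adjusted over the list alone, MSX2 from 0.669 ± 0.947 to 110 ± 57.7 RPM (adjusted p = 4.24e-06, and 0.00917 with an estimated correlation). Primed pluripotency genes fell in 8 of 12 cases and 1, SFRP2, rose, with the same counts adjusted over the list alone (adjusted p = 5.46e-05, and 0.0205 with an estimated correlation). Primitive streak genes went both ways: T rose to 255 ± 15.2 RPM with EVX1, LHX1 and WNT3, EOMES, SP5, NODAL and LEFTY1 fell, and the list's mean was above 0 while its median and test were below (adjusted p = 0.875). Cholesterol synthesis genes fell in 5 of 13 cases, also adjusted over the list alone, among them INSIG1, HMGCS1 and CYP51A1 (adjusted p = 0.0001, and 0.0205 with an estimated correlation).

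**Figure D1:**
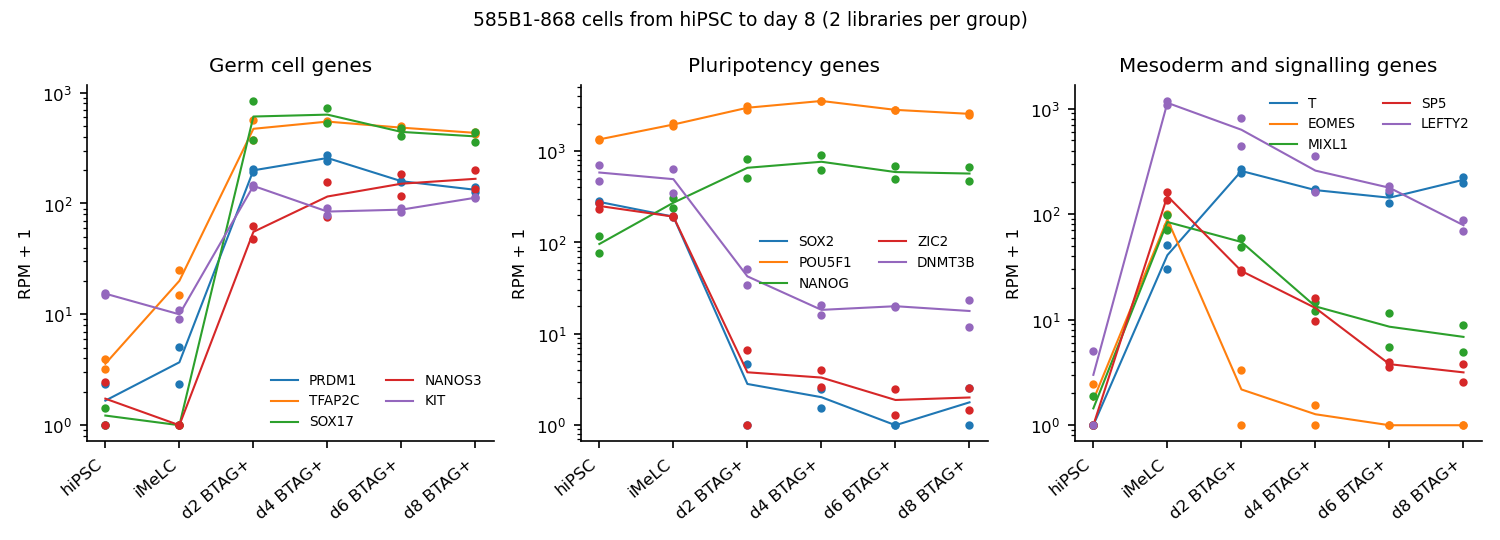
Levels of named genes (RPM plus 1, log axis) in the 585B1-868 series from hiPSC through iMeLC to BTAG+ cells at days 2, 4, 6 and 8; points are the 2 libraries of each group and lines join the means. SOX17 lay at 0 in iMeLCs and at 608 RPM at day 2, and SOX2 fell from 191 to 1.83 RPM between the same stages.

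Between days 2 and 4 no early germ cell gene was called in BTAG+ cells, and 2 of 16 rose adjusted over the list alone. NODAL fell from 70.5 ± 18.6 to 10.9 ± 6.80 RPM, LEFTY1 from 354 ± 60.7 to 60.4 ± 6.27 RPM, MIXL1 from 53.4 ± 7.74 to 12.3 ± 1.80 RPM and the muscle actin gene ACTA1 from 572 ± 198 to 32.0 ± 3.97 RPM. KLRB1, a lectin-like receptor gene, rose from 8.08 ± 0.742 to 88.9 ± 18.7 RPM (log2 change 3.29, SE 0.30, adjusted p = 1.48e-06), KLF4 from 126 ± 20.6 to 357 ± 1.73 RPM and the methyltransferase cofactor DNMT3L from 3.02 ± 2.14 to 18.4 ± 3.90 RPM. PRDM1, TFAP2C and SOX17 stood at 256 ± 22.7, 547 ± 9.53 and 632 ± 139 RPM at day 4. GJA5, TSHZ3, IL13RA2, BNC1, HCAR2, MX1 and PLEKHA7 were the other large rises, and VIL1, EFNA5, EDIL3, DNAL1, DEPTOR and PDF the other large falls. PDF overlaps another gene and its values are shares of reads, so that fall is uncertain. Of 10775 genes 336 were called, 189 higher and 147 lower; without d2 replicate 2 the count was 208, without d4 replicate 2 it was 167, with library weights 125, and 531 without the shallow libraries. Primitive streak genes fell in 3 of 12 cases, 5 adjusted over the list alone (camera adjusted p = 3.05e-05, and 0.0458 with an estimated correlation). Cholesterol synthesis genes rose in 3 of 13 cases, also adjusted over the list alone, INSIG1 and HMGCS1 among them (adjusted p = 0.00323, and 0.12 with an estimated correlation).

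From day 4 to day 6 fewer genes were called than in the step before. COL3A1 rose from 10.5 ± 2.25 to 69.6 ± 9.02 RPM (log2 change 2.62, SE 0.53, adjusted p = 0.0131), LUM from 2.95 ± 2.25 to 25.2 ± 14.9 RPM and the phospholipase gene PLCD4 from 12.6 ± 7.07 to 116 ± 8.18 RPM. HOXD1 fell from 77.7 ± 7.11 to 6.90 ± 0.776 RPM and LRAT, a retinol-modifying enzyme, from 177 ± 17.4 to 27.8 ± 3.52 RPM. MS4A12, ASPA, TUBB4, FBP1 and PDF were the other large rises; OLFM3, SPINK5, KCNJ8, CADPS, HKDC1 and LXN were the other large falls. In all 139 of 10775 genes were called, 48 higher (34.5%) and 91 lower, 231 with a replicate block, and with quantile normalization 47.2% of calls were higher. The count was 237 without d4 replicate 1, 17 without d4 replicate 2 and 40 without d6 replicate 2. Fibroblast and mesenchyme genes rose in 4 of 9 cases, also adjusted over the list alone (camera adjusted p = 2.53e-05, and 0.0769 with an estimated correlation). No early germ cell gene was called among 16, and 1 fell adjusted over the list alone (adjusted p = 0.399).

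Between days 6 and 8 only NEFL, a neurofilament gene (hg19 chromosome 8, 24808468 to 24814235), was called. It fell from 5.41 ± 1.33 RPM (25 reads) to 1 read, a ratio of 30.03 with an interval of 4.92 to 1233. At an unadjusted p under 0.05, 638 of 10775 genes differed, and 10 were called with a replicate block. The count was 61 without d6 replicate 1, 2 without d6 replicate 2, 43 without d8 replicate 1 and 0 without d8 replicate 2. PRDM1, TFAP2C, SOX17 and NANOS3 stood at 132 ± 9.89, 432 ± 8.72, 402 ± 58.4 and 166 ± 44.9 RPM at day 8, and no list of the 16 tested passed, nor with a replicate block. Without the shallow libraries 3 lists passed, which is no support for a change, since each group then held 1 library and its spread was borrowed from sets whose replicates agreed better.

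Against hiPSCs, day 6 BTAG+ cells held early germ cell transcripts and lower levels of most primed pluripotency transcripts. SOX17 stood at 441 ± 52.0 RPM against 2 reads in hiPSCs (ratio 1078, interval 298 to 8908) and NANOS3 at 150 ± 49.7 RPM against 1 read (ratio 898, interval 161 to 35530). TFAP2C rose from 2.59 ± 0.512 to 482 ± 23.6 RPM and PRDM1 from 0.667 ± 0.943 to 158 ± 2.06 RPM. CRHBP, a corticotropin-releasing hormone binding protein, reached 593 ± 203 RPM and the growth factor IGF1 372 ± 13.1 RPM, both from 0 reads, at least 1191-fold and 631-fold higher. KLRB1 reached 363 ± 9.50 RPM against 1 read in hiPSCs, and SOSTDC1, LAMA4, PCP4L1 and FAM20A were the other large rises. SOX2 went from 277 ± 14.1 RPM to 0 reads, at least 392-fold lower, and SFRP1 fell from 1133 ± 313 to 5.26 ± 1.13 RPM (log2 change -7.48, SE 0.30). ZIC2, PTPRZ1, USP44, BCAT1, CHGA and CUZD1 were the other large falls. Of 10775 genes 3155 were called, 1701 higher and 1454 lower.

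Each of the 21 gene lists was counted at day 6 against hiPSC over all genes tested, and the counts adjusted over the list alone were equal except where given. Early germ cell genes rose in 13 of 16 cases and PRDM14 fell (camera adjusted p = 2.49e-11, and 0.000172 with an estimated correlation). BMP targets rose in 9 of 11 cases, 11 adjusted over the list alone (adjusted p = 6.36e-08, and 0.00316 with an estimated correlation). Primitive streak genes rose in 9 of 12 cases, T to 142 ± 23.8 RPM (adjusted p = 0.000134, and 0.0234 with an estimated correlation). Trophoblast and amnion genes rose in 5 of 5 cases, GATA2 and GATA3 most (adjusted p = 0.000396, and 0.0159 with an estimated correlation). KLF4, TFCP2L1, KLF5 and TBX3 of 6 naive pluripotency genes rose (adjusted p = 0.00121, and 0.0322 with an estimated correlation). WNT targets rose in 4 of 6 cases (adjusted p = 0.00461, and 0.0784 with an estimated correlation). Primed pluripotency genes fell in 9 of 12 cases, ZIC2 and DUSP6 among them, and CDH2 rose (adjusted p = 1.35e-05, and 0.0173 with an estimated correlation). Cell cycle genes fell in 7 of 16 cases, CCNE1 and CDC20 among them (adjusted p = 1.75e-05, and 0.0264 with an estimated correlation). Core pluripotency genes fell in 6 of 12 cases, SOX2 and TDGF1 most, while NANOG and POU5F1 rose (adjusted p = 0.0216, and 0.0458 with an estimated correlation).

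The other 12 lists did not pass the camera test or held too few tested genes for it. DNMT3L and TET2 rose and DNMT3B fell among 10 DNA methylation genes, the mean lying above 0 and the median and test below (adjusted p = 0.913). The histone methyltransferase gene EHMT2 fell from 86.7 ± 5.95 to 28.9 ± 3.34 RPM with CBX2, EED and EZH2 among 11 histone repression genes, whose mean was below 0 and median above (adjusted p = 0.361). HMGCS1 and FDPS fell among 13 cholesterol synthesis genes (adjusted p = 0.152). Of 13 glycolysis and hypoxia genes 2 rose and 2 fell, 3 adjusted over the list alone, with the mean above 0 and the median below (adjusted p = 0.656). Of 14 stress and immediate early genes 3 rose and 1 fell, 2 adjusted over the list alone (adjusted p = 0.747). POSTN, COL3A1, LUM and COL6A3 rose and COL1A1 fell among 9 fibroblast and mesenchyme genes (adjusted p = 0.29). GATA4 and HHEX rose and AFP and FOXA3 fell among 5 endoderm genes, with mean and median of opposite sign (adjusted p = 0.913). In the lists too short to test, later germ cell genes had HORMAD1 higher and DAZL and TEX15 lower of 4, neural genes TUBB3 higher and MAP2 lower of 3, HOX genes HOXD1 higher of 2. Gonadal somatic genes had GATA4 higher and SOX9 lower of 2, and blood and endothelium genes LYZ higher and TEK and KDR lower of 3.

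A further set of 585B1-868 libraries, marked in the labels with a star that is not explained, and the reporter-free line 585A1, sorted on EpCAM and CD49f (CSM+), were compared at day 6 in the same way. In the star set SOX17 stood at 750 ± 138 RPM, NANOS3 at 269 ± 5.33 RPM and CRHBP at 451 ± 41.2 RPM at day 6, and ZIC2, NPTX1 and SOX2 were the largest falls. There 2786 of 10775 genes were called, 1434 higher and 1352 lower. In 585A1 CSM+ cells SOX17 stood at 507 ± 15.5 RPM, CXCR4 at 458 ± 46.7 RPM, PRDM1 at 99.3 ± 27.4 RPM and NANOS3 at 188 ± 25.4 RPM, and SOX2, ZIC2 and CUZD1 were the largest falls. There 3015 genes were called and 43.9% of calls were higher, or 55.4% with trimmed-mean scaling, which moved the median of all genes from -0.17 to 0.02. Of the early germ cell genes 13 of 16 rose in the star set and 14 of 16 did in 585A1, also adjusted over the list alone (camera adjusted p = 1.65e-13 and 2.15e-13, and 7.30e-05 and 7.61e-05 with an estimated correlation).

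In iMeLCs of 585A1 LEFTY2 rose from 7.23 ± 1.13 to 1401 ± 81.3 RPM and SP5 reached 165 ± 27.2 RPM against 1 read in hiPSCs, with GLIPR1L1 the next rise; NPTX1, CUZD1 and SFRP1 were the largest falls. Of 10775 genes 792 were called. Of these 38.0% were higher, against 51.6% with trimmed-mean scaling, which moved the median of all genes from -0.13 to 0.00, and 55.1% with quantile normalization. The count was 387 without hiPSC replicate 1, 434 without hiPSC replicate 2, 417 without iMeLC replicate 1 and 434 without iMeLC replicate 2, but 1347 with library weights and 1309 without the shallow libraries of 585B1-868. Primitive streak genes rose in 8 of 12 cases, and adjusted over the list alone 9 rose and 1 fell (camera adjusted p = 1.16e-19, and 0.000188 with an estimated correlation).

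The number of genes whose day 6 change differed between sets depended on how replicates were handled. With a replicate block it was 70 between the star set and the first series and 42 between the lines. In the first series deviations by replicate number, which there goes with depth, correlated across genes at 0.228 to 0.32. Without a block, between the star set and the first series 4 genes were called and 774 had an unadjusted p under 0.05. Their log2 changes, in the star set against the first series, were 0.504 against -1.32 for CNTNAP2 (difference 1.82, SE 0.31, adjusted p = 0.0261), 0.0174 against 4.42 for RAI1 (-4.40), -1.15 against 3.21 for TUBB4 (-4.36) and -2.15 against 0.222 for D4S234E (-2.37). That count was 57 without hiPSC replicate 1, 2 without hiPSC replicate 2, 25 without d6 replicate 1, 1 without d6 replicate 2, and 2 without either star d6 library. Between 585A1 and 585B1-868 4 genes were called and 874 had an unadjusted p under 0.05. NLRP7 (5.62, SE 0.65, adjusted p = 0.000279) stood at 81.8 ± 12.9 RPM in 585A1 CSM+ cells and at 0 in day 6 BTAG+ cells. SOX15 (-2.17), NECAB1 (-1.95) and TMEM64 (-1.68) changed less in 585A1, where the median of all genes moved by -0.13, or 0.01 with trimmed-mean scaling. Its count was 64 without hiPSC replicate 1, 8 and 1 without d6 replicates 1 and 2, 1 without 585A1 hiPSC replicate 1, and 0 and 2 without CSM+ replicates 1 and 2.

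The genotype set compares wild-type (wt), heterozygous (het) and knockout (ko) lines before and after induction from iPSCs; the labels do not name the altered gene. The 2 wt and the 2 ko libraries are different lines, wt cells were sorted on the TFAP2C reporter alone (AG+) and het and ko cells on both reporters (BTAG+). Sorted cells of every genotype were thus selected for the TFAP2C reporter, which limits what TFAP2C levels can show. In iPSCs PRDM1 stood at 8.38 ± 2.51 RPM in ko (47 reads) against 1 read in wt, a ratio of 41.4 with an interval of 7.08 to 1671 (adjusted p = 7.14e-07), and at 24.9 RPM in the 1 het library. RBM24 and SEPT6 fell, and ARMCX5-GPRASP2 was higher, an uncertain call since it is a readthrough of overlapping genes. These 4 of 10690 genes were called in ko against wt iPSCs, 355 had an unadjusted p under 0.05, and the count was 1 without wt replicate 2 and 2 without ko replicate 2.

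At day 2 the ko cells held several transcripts at levels far above wt. PTPRZ1, a receptor phosphatase, stood at 161 ± 81.1 RPM in ko and 4.24 ± 1.70 in wt (log2 change 4.89, SE 0.32, adjusted p = 3.44e-09), and the adhesion gene FLRT2 at 42.3 ± 5.56 and 1.78 ± 0.707 RPM. BCAT1, NR4A3, CALB1 and the pepsinogen genes PGA3 and PGA5 were also among the large rises, the last pair being close paralogs and so uncertain. MBP stood at 3.56 ± 0.513 RPM in ko and 47.7 ± 12.7 in wt, and ELOVL3 at 3 reads against 15.5 ± 4.75 RPM in wt (ratio 32.3, interval 10.7 to 159). SELM, KRT7, CEBPA, FGF18, SLC43A1 and the uncertain ARMCX5-GPRASP2 were the other large falls. PRDM1 was not called at 85.3 ± 17.7 RPM in ko, 172 ± 50.2 in wt and 138 in het, nor TFAP2C at 326 ± 36.8, 243.5 ± 95.05 and 309 RPM. Of 10690 genes 328 were called, 177 higher and 151 lower, and 195 without wt replicate 1. KRT7 and GATA2 fell among 8 trophoblast and amnion genes, also adjusted over the list alone (camera adjusted p = 0.000159, and 0.43 with an estimated correlation). Camera called 7 of 16 lists here, and 0 with an estimated correlation. The early germ cell list was lower in ko (adjusted p = 0.0392), but did not pass with a replicate block (0.0544), no filter (0.0595) or a pseudocount of 0.1 (0.102). The core pluripotency (0.035), neural (0.035), primitive streak (0.0356) and stress and immediate early (0.0356) lists also passed.

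By day 4 many genes differed between ko and wt cells, among them germ cell regulators that went both ways. POU4F1, a neuronal POU factor, stood at 187 ± 12.2 RPM in ko, 1.68 ± 0.149 in wt and 13.5 in het (log2 change 6.13, SE 0.52, adjusted p = 6.19e-09). The matrix gene FN1 stood at 2593 ± 60.5, 59.1 ± 1.95 and 470 RPM, and LRP2, a megalin gene, at 75.4 ± 9.34, 0.938 ± 0.905 and 3.94 RPM in the same order. T stood at 0.865 ± 0.0860 RPM in ko, 71.7 ± 3.55 in wt and 22 in het (log2 change -5.28, SE 0.42), and LEFTY2 at 11.01 ± 0.731, 259 ± 25.7 and 94.6 RPM. NANOS3 fell from 86.0 ± 6.08 RPM in wt to 5.84 ± 0.839 in ko (log2 change -3.67, SE 0.45), with 72.2 RPM in het. PRDM1 fell from 189 ± 13.4 to 41.6 ± 6.17 RPM, with 101 RPM in het, while TFAP2C (209 ± 42.3 in wt, 292 ± 33.7 in ko, 265 in het) and SOX17 (454 ± 23.5, 341 ± 25.4 and 453 RPM) were not called.

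PTPRZ1, CALB1, AMOT, POMC and ABCG2 were the other large rises in ko cells at day 4, and DLK1, LEFTY1, TRPC6, ACTG2, PNMA2 and SCUBE2 the other large falls. Of 10690 genes 1632 were called, 1109 higher (68.0%) and 523 lower, with 56.7% higher under quantile normalization. Trophoblast and amnion genes rose in 7 of 8 cases, 8 adjusted over the list alone, TFAP2B, VTCN1 and GABRP most (camera adjusted p = 6.07e-06, and 0.192 with an estimated correlation). BMP targets rose in 6 of 11 cases, also adjusted over the list alone, HAND1 from 29.6 ± 1.19 to 298 ± 45.6 RPM (adjusted p = 0.000173, and 0.192 with an estimated correlation). Primitive streak genes fell in 7 of 11 cases and SP5 rose, 2 rising adjusted over the list alone (adjusted p = 0.00647, and 0.301 with an estimated correlation). Neural genes POU4F1, ISL1 and NES rose among 5, also adjusted over the list alone (adjusted p = 0.00876, and 0.192 with an estimated correlation). The early germ cell list split: NANOS3, PRDM1 and DND1 fell and TFAP2A and DPPA3 rose of 15, also adjusted over the list alone (adjusted p = 0.0611). TFAP2A stood at 134 ± 3.601 RPM in ko, 8.67 ± 3.33 in wt and 46.6 in het. The gate differed with the genotype, so neither can be told apart from the other in these comparisons.

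**Figure D2:**
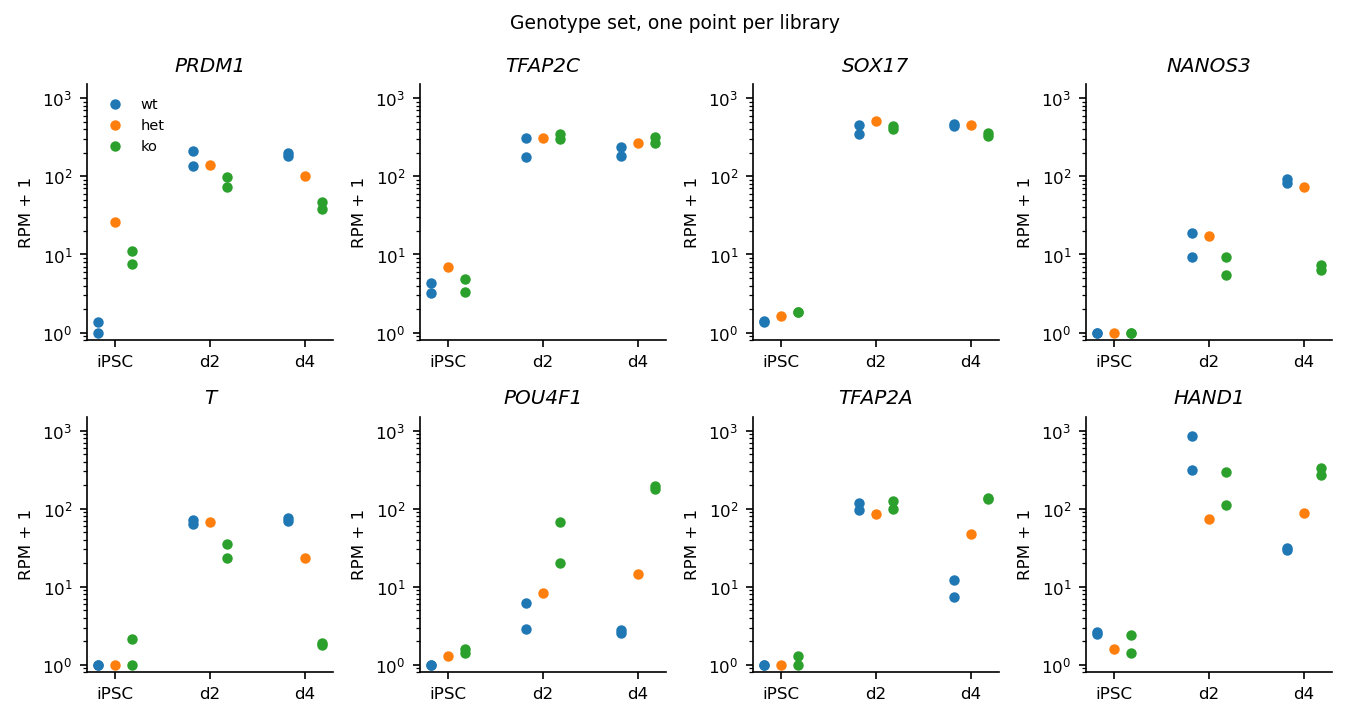
Levels of 8 genes (RPM plus 1, log axis) in wt, het and ko libraries at the iPSC stage, day 2 and day 4; each point is 1 library. At day 4 T lay at 71.7 RPM in wt, 22 in het and 0.865 in ko, and POU4F1 at 1.68, 13.5 and 187 RPM.

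In wt lines day 4 AG+ cells against iPSCs gave 3245 calls of 10690 genes, 1785 higher and 1460 lower. SOX17 reached 454 ± 23.5 RPM against 2 reads, LAMA4 484 ± 85.0 RPM and CRHBP 217 ± 76.0 RPM. ZIC2 went from 380 ± 43.8 RPM to 0 reads, at least 830-fold lower, and SOX2 fell from 435 ± 20.3 to 1.05 ± 1.04 RPM, with USP44 the remaining large fall. Early germ cell genes rose in 12 of 15 cases, also adjusted over the list alone (camera adjusted p = 7.76e-11, and 0.0371 with an estimated correlation). The change from iPSC to day 4 itself differed between ko and wt for 1196 genes. Of these 832 were higher in ko (69.6%, or 58.4% with quantile normalization) and 364 lower. POMC (6.34, SE 0.72, adjusted p = 1.99e-06), FN1 (5.57) and POU4F1 (5.55) differed most upward, and T (-5.84), ACTG2 (-5.47) and the uncertain ARMCX5-GPRASP2 (-5.90) most downward.

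In mouse, epiblast-like cells (EpiLCs) held naive pluripotency transcripts at lower levels than embryonic stem cells (mESCs). Dnmt3a rose from 5.47 ± 0.272 to 310 ± 122 RPM (log2 change 5.53, SE 0.34, adjusted p = 1.34e-09). Fgf5 stood at 101 ± 62.2 RPM against 1 read in mESCs (ratio 171, interval 30.4 to 6796) and Pou3f1 at 113 ± 35.1 RPM against 3 reads (ratio 63.0, interval 21.3 to 308). Tfcp2l1 fell from 327 ± 48.2 to 6.62 ± 6.66 RPM and Tdh, a threonine dehydrogenase, from 897 ± 0.197 to 9.89 ± 0.435 RPM. Klf4 went from 102 ± 18.7 RPM to 1 read, and the germ cell regulator Prdm14 (mm10 chromosome 1, 13113457 to 13127163) from 46.0 ± 17.0 to 0.567 ± 0.801 RPM. Car4, Tmem59l, Cgnl1, Mmp25 and Enpp2 were the other large rises and Jam2, Klf2, Tcl1, Tbx3 and Sp5 the other large falls. Of 10041 genes 1274 were called, 605 higher and 669 lower. All 10 naive pluripotency genes tested fell, also adjusted over the list alone (camera adjusted p = 9.31e-16, and 0.0273 with an estimated correlation). Primed genes rose in 9 of 14 cases, 10 adjusted over the list alone (adjusted p = 4.10e-09, and 0.0251 with an estimated correlation). Dnmt3a and Dnmt3b rose and Tet2 fell among 9 DNA methylation genes, also adjusted over the list alone, and that list did not pass (adjusted p = 0.106).

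Mouse day 2 cells positive for the Blimp1 reporter (BV+) held streak and BMP transcripts at high levels. T (mm10 chromosome 17, 8434423 to 8442496) stood at 1098 ± 372 RPM against 1 read in EpiLCs (ratio 2021, interval 363 to 79830). The small proline-rich genes Sprr2a1 and Sprr2a3 reached 2594 ± 494 and 1989 ± 408 RPM from 0 reads; they are close paralogs, so their reads may not be separable. Id1 rose from 2.09 ± 0.247 to 595 ± 85.0 RPM and Hand1 from 0.567 ± 0.801 to 735 ± 299 RPM. Sox17 reached 37.3 ± 10.9 RPM from 0 reads, Prdm1 rose from 2.18 ± 1.73 to 131 ± 20.8 RPM, and Dnmt3l, Fgf4 and Fgf5 were the largest falls. Of 10041 genes 2782 were called, 1919 higher (69.0%) and 863 lower. The day 2 libraries came from 1 ng of RNA and the EpiLC libraries from 10 ng. Spike-in signals were 21564 and 30401 RPM at day 2 against 246 and 69.0 RPM in EpiLCs. Depths were 5.73 and 8.30 against 0.883 and 1.04 M reads. Stage is therefore not separated from library preparation in this comparison. The median of all genes was 0.24, or 0.02 with trimmed-mean scaling, where 54.2% of calls were higher, and 48.4% were with quantile normalization. Without d2 replicate 1 the count was 1727 and without d2 replicate 2 it was 1738. BMP targets rose in 9 of 10 cases and streak genes in 10 of 13, also adjusted over the list alone (camera adjusted p = 4.30e-08 and 9.74e-07, and 0.0239 for both with an estimated correlation). Early germ cell genes rose in 10 of 14 cases and Utf1 fell, also adjusted over the list alone (adjusted p = 0.00015, and 0.131 with an estimated correlation). Cholesterol synthesis genes fell in 10 of 13 cases, also adjusted over the list alone, Sqle from 301 ± 65.7 to 53.1 ± 17.2 RPM (adjusted p = 2.60e-08, and 0.0479 with an estimated correlation).

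By day 6 mouse cells positive for both the Blimp1 and stella reporters (BVSC+) held naive and germ cell transcripts, and T was at 0 reads. Prdm14 stood at 132 ± 16.5 RPM against 1 read in EpiLCs (ratio 256, interval 45.4 to 10150). Dppa3 (stella) rose from 22.7 ± 6.35 to 922 ± 37.7 RPM, Tfap2c from 3.14 ± 0.371 to 201 ± 43.6 RPM and Sox2 from 63.5 ± 3.10 to 221 ± 9.67 RPM. The homeobox genes Rhox6 and Rhox9 rose to 550 ± 68.5 and 926 ± 29.9 RPM, and BC048679 from 0 reads to 419 ± 12.5 RPM, at least 269-fold higher. Dnmt3b fell from 909 ± 245 to 4.53 ± 0.477 RPM (log2 change -7.34, SE 0.32, adjusted p = 6.54e-12), Uhrf1 from 113 ± 30.3 to 16.3 ± 0.675 RPM, and Fgf4 from 217 ± 16.8 RPM to 0 reads. Lcp1, Ap3b2, Klf2 and H19 were the other large rises; Calca, Pla2g1b, Prps1, Ppp1r1a, Lrp2 and Tcfl5 were the other large falls. Of 10041 genes 2218 were called, 1244 higher and 974 lower, the median of all genes being 0.11, or -0.05 with trimmed-mean scaling. Early germ cell genes rose in 10 of 14 cases, also adjusted over the list alone (camera adjusted p = 2.21e-08, and 0.182 with an estimated correlation). Primed genes fell in 10 of 14 cases, also adjusted over the list alone (adjusted p = 2.14e-07, and 0.0412 with an estimated correlation). Naive genes rose in 6 of 10 cases, 8 adjusted over the list alone (adjusted p = 2.64e-05, and 0.182 with an estimated correlation).

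Between days 4 and 6 in mouse Rhox5 rose from 34.6 ± 15.0 to 529 ± 24.6 RPM (log2 change 3.96, SE 0.30, adjusted p = 3.38e-07), Rpl39l from 5.50 ± 0.684 to 117 ± 37.3 RPM and Fkbp6 from 0 reads to 14.7 ± 5.00 RPM. Fam171b, Dclk1 and Fndc3c1 were the largest falls. Of 10041 genes 104 were called, 56 higher and 48 lower; the count was 29 without d4 replicate 1, 51 without d4 replicate 2, 36 without d6 replicate 1, 58 without d6 replicate 2 and 177 with library weights. Hormad1 and Piwil2 rose among 11 later germ cell genes, 8 adjusted over the list alone (camera adjusted p = 7.64e-07, and 0.18 with an estimated correlation).

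Cynomolgus gonadal germ cells (cyPGCs), single cells from the genital ridge at embryonic days 43 (7 cells), 50 (5 cells) and 51 (7 cells), were set beside 8 embryonic stem cells (cyESCs) without a test, since the labels name no animals. SDs are over cells. SOX2 stood at 399 ± 154 RPM in cyESCs and at 2.03 ± 1.27, 1.99 ± 1.74 and 1.68 ± 0.916 RPM at the 3 ages. DDX4, a germ cell helicase, was at 0 reads in cyESCs and at 107 ± 54.3, 124 ± 54.3 and 123 ± 68.2 RPM, at least 747-fold higher over the 3 ages. DNMT3L was at 0 reads and then 246 ± 76.3, 103 ± 42.9 and 118 ± 109 RPM, and SOX15 at 0.724 ± 2.05 and then 351 ± 116, 283 ± 146 and 194 ± 81.1 RPM. DNMT3B stood at 907 ± 456 RPM in cyESCs and 31.0 ± 12.7, 38.1 ± 26.1 and 29.9 ± 29.7 RPM in cyPGCs. The incretin gene GIP had the largest ratio, from 0.273 ± 0.625 to 418 ± 149, 733 ± 717 and 421 ± 179 RPM. NLRP2, NLRP7, PPARA, TCL1B, TUBA3C, COL3A1 and GLB1L3 were the other large rises in mean level, and SPP1, USP44, ARHGAP36, ZSCAN10, NPPB, TRIB3, VTCN1, CBS and THBS1 the other large drops.

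Of 12 early germ cell genes measured in cynomolgus 10 were higher at all 3 ages and PRDM14 was lower, at 298 ± 115 RPM in cyESCs and 20.5 ± 8.49, 75.4 ± 42.2 and 31.1 ± 19.2 RPM in cyPGCs. Of 20 later germ cell genes with values, 10 passed the filter, a mean of at least 10 RPM in cyESCs or over the cyPGC ages. NANOS2 and BOLL, among those left out, had no read in any cell. All 10 had higher means at all 3 ages, DAZL from 1.54 ± 2.96 RPM to 23.9 ± 52.6, 125 ± 155 and 117 ± 90.3 RPM. At E43 DAZL rested on 2 of 7 cells, at 25.2 and 141 RPM, and the median cell held 0.302 RPM. Primed pluripotency genes were lower at all ages in 8 of 10 cases. The median log2 ratios of these 3 lists were 4.12, 5.16 and -3.96, or 4.12, 6.34 and -3.96 with genes at 0 reads placed at 3 reads over the group. They lay at percentiles 100, 100 and 0 of 10000 random lists matched on mean level. The gonadal somatic list (median 4.799, or 6.01 with such genes at the floor) and the endoderm list (3.47, or 4.09) also lay at percentile 100, and the fibroblast and mesenchyme list (2.50) at 99.9. A gene under 10 RPM in cyESCs could pass the filter only through cyPGCs, and a gene under 10 RPM in cyPGCs only through cyESCs. In the early germ cell list NANOS3 (0 reads) and SOX15 (0.724 RPM in cyESCs) passed through cyPGCs alone. Genes with 0 reads in cyESCs were 1 of 12 early and 5 of 10 later germ cell genes. They were also 4 of 9 gonadal somatic and 2 of 6 endoderm genes. Other members, such as DAZL and COL3A1, had reads there but under 10 RPM. The counts and ranks of all these lists were thus partly fixed in advance and are no support for a change. By age, E43, E50 and E51, the medians were 5.964, 2.945 and 3.913 for the gonadal somatic list, 3.255, 2.217 and 4.106 for endoderm and 2.642, 0.137 and 1.215 for fibroblast and mesenchyme, where 3 of 6 genes were higher at all ages. Gonadal somatic genes were higher at all ages in 8 of 9 cases, WT1 from 0 reads to 166 ± 198, 22.2 ± 32.5 and 54.9 ± 129 RPM, with SDs above the means, and at E51 it was read in 2 of 7 cells, at 39.7 and 345 RPM. Means at E51 rested on few cells for LHX9 and TCF21 too, with medians of 0 and 0.817 RPM, but less so for GATA4 (114) and NR2F2 (49.4). There the list summed to 1881 RPM in the highest cell, with a median of 114. COL3A1 stood at 0.0381 ± 0.108 RPM in cyESCs and 329 ± 450, 12.1 ± 11.1 and 87.9 ± 139 RPM in cyPGCs.

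**Figure D3:**
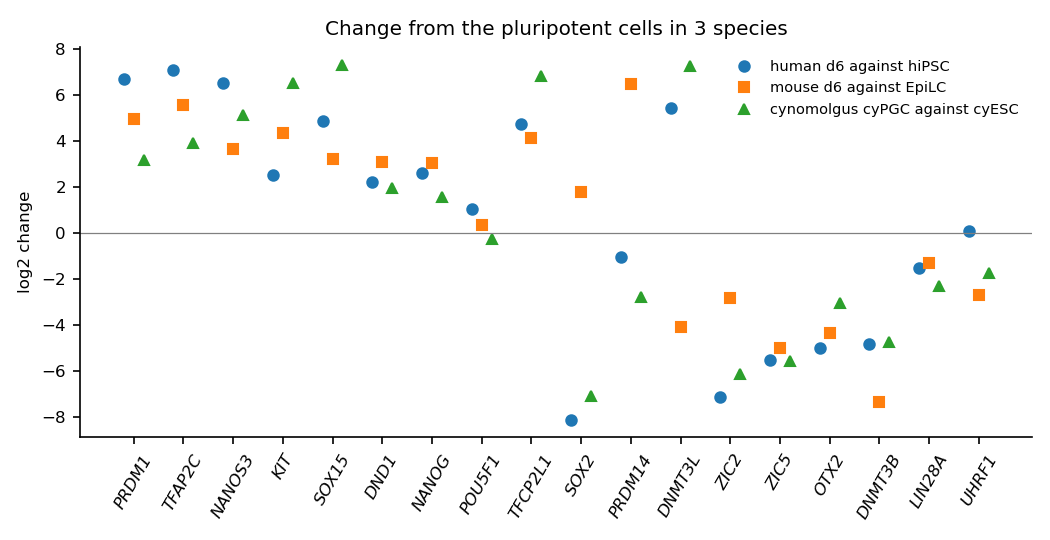
Change in level (log2, vertical axis) of named genes from the pluripotent cells: human day 6 against hiPSC, mouse day 6 against EpiLC, and cyPGC against cyESC. SOX2 was -8.12 in human, 1.78 in mouse and -7.11 in cynomolgus.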

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

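Tests on differentiated cells among ko iPSCs, on the share of germ cell-like cells in the ko sort and on the signal lost by abundant genes in mouse day 2 cells were chosen only after the result was seen.

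The change from iPSC to day 4 differed between ko and wt lines for 1196 genes, by a test of the difference itself. The day 6 change differed between the star set and the first series for 4 genes: CNTNAP2 (1.82), RAI1 (-4.40), TUBB4 (-4.36) and D4S234E (-2.37). Between 585A1 and 585B1-868 it differed for 4 genes: NLRP7 (5.62), SOX15 (-2.17), NECAB1 (-1.95) and TMEM64 (-1.68). With a replicate block these counts were 70 and 42; replicate number goes with depth in the first series.

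Single cells were compared within their group on 8 measures. A cell stood apart in 3 of 32 combinations of a measure and a group, where chance gives about 1 in 20 for normal values, which summed levels need not be. The measure finds a lone cell and passes over groups with several high cells. At E43 the gonadal somatic list summed to 2019 RPM in the highest cell and 1645 in the nearest, with a median of 665. Among the 5 cyPGCs of E50 the summed level of the core pluripotency list was 4540 RPM in the highest cell and 3165 in the nearest. Among the 7 cyPGCs of E51 the gonadal somatic list summed to 1881 RPM in the highest cell and 502 in the nearest. The same cell had 13730 genes detected, against 11280 in the nearest. It held WT1 at 345 RPM, NR2F2 at 590.3 RPM and COL1A1 at 1191 RPM, together with POU5F1 at 612 RPM. No explanation was tested for these cells.

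PRDM1 was read in ko iPSCs, and the 1 het iPSC library, outside the tests, held 24.9 RPM against at most 0.367 RPM in wt iPSCs. Differentiated germ cell-like cells among the ko iPSCs were argued against: SOX17, TFAP2C and NANOS3 together rose by 0.0385 or less of the amount that the PRDM1 share called for. A transcript of the altered locus was tested by whether the het library exceeded wt, and its 24.9 RPM (81 reads) did. That fitted the explanation, but the het library held more PRDM1 reads than either ko library, with 23 and 24. Their depths were 3.25 M reads in het and 2.36 and 3.48 M in ko. The explanation was not tested against that order, and differentiated cells were looked for in the ko libraries alone. This explanation stays a hypothesis for the ko lines, since the labels do not name the altered gene and there was 1 het library.

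At day 4, 1109 genes were higher in ko than in wt cells, with a median of 1.68. A smaller share of germ cell-like cells in the ko sort would lower the early germ cell genes induced in wt alike. They spread over 7.52 on the log2 scale, with TFAP2A higher (3.85) and NANOS3, PRDM1 and DND1 lower. The rise rests on TFAP2A alone, and trophoblast and amnion genes also rose in these cells. Other cells holding TFAP2A could raise it, so it cannot exclude a mixture. The falls were unequal, -3.67 for NANOS3 and -0.41 for SOX17 (not called). A smaller share alone gives that only if the other cells held some of these genes, which was not tested. The sorting gate cannot be told apart from the genotype. Over these genes het cells, with the gate of ko, exceeded wt by a median of 0.71, and intact 585B1-868 cells with that gate by 0.0689. The first lay between the bounds set for it, 0.42 and 0.84, and a biological effect of the genotype stays open.

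In mouse day 2 cells 69.0% of calls were higher than in EpiLCs. Greater depth was argued against: with day 2 libraries thinned to the depth of the others, 66.9% of calls were higher. A few abundant genes shifting the per-million scale were argued against as the whole cause: the signal lost by the 20 genes that fell most lifted the others by 0.0482 on the log2 scale (0.0375 to 0.0588 over 4 library pairs), where the median of all genes was 0.24. A shift spread over more genes stays open, as the 100 genes that fell most gave 0.15 and, rescaled without them, 60.5% of calls were higher. RNA input also differed at day 2 and was not tested, and no biological explanation was tested.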

How the results depend on the processing

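Library weights, leaving out shallow libraries, leaving out the mouse day 2 libraries and the crossed pairing were chosen only after the data were seen. The planned count model was not run, since whole reads could not be recovered for all values. The cause was not tested for any change given here, except that a higher filter tests fewer genes.

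Of 15464 alternative values over 1160 gene results, 14146 (91.5%) kept their direction and side of the threshold, 1318 were weaker and 0 reversed. All 1160 had been called in the main fit, some as its largest changes, so none could be counted as stronger. The 91.5% thus describes called genes picked from these data and not genes in general. In every alternative 787 of the 1160 held. That share differed between comparisons. It was 89 of 119 for d6 against hiPSC, but 9 of 35 for d4 against d2, 3 of 23 for d6 against d4 and 0 of 4 for ko against wt iPSCs. In cynomolgus 935 of 1002 values stayed within those bounds, 36 were weaker, 30 stronger and 1 reversed: JUN, cynomolgus, at 1.31, was -0.0708 without E43 cells.

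With no filter, the counts were 7 for d8 against d6, 10 for the star set minus the first series, 15 for 585A1 minus 585B1-868, 2 for ko against wt iPSCs and 26 for mouse d6 against d4. With a filter at 30 they were 2008 for 585A1 d6, 1033 for ko against wt at d4, 2072 for wt d4 and 849 for EpiLC. With a pseudocount of 0.1 they were 88 for d6 against d4, 7 for d8 against d6, 2 for 585A1 minus 585B1-868, 7 for ko against wt iPSCs and 54 for mouse d6 against d4. With a pseudocount of 10 the human counts were 275 for iMeLC, 1339 for d2, 207 for d4, 0 for d8, 1977 for d6 against hiPSC, 1758 in the star set, 453 for 585A1 iMeLC, 1831 for 585A1 d6 and 29 for the star set minus the first series. It gave 1, 209 and 903 for ko against wt iPSCs, d2 and d4, 1919 for wt d4, 841 for EpiLC and 1473 for mouse d6 against EpiLC.

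Trimmed-mean scaling gave 2 for d8 against d6. Quantile normalization gave 0 for d8, 8 for the star set minus the first series, 2 for 585A1 minus 585B1-868 and 2 for ko against wt iPSCs. Library weights gave 291 for iMeLC, 125 for d4 against d2, 46 for d6 against d4, 0 for d8, 1347 for 585A1 iMeLC, 7 and 7 for the differences between day 6 changes, and 177 for mouse d6 against d4. The 2 libraries of a group always got the same weight, so a shallow library was not set below its deep partner. Weights were 0.595 to 0.695 in the first series and 1.34 to 2.01 in the star set and 585A1. A replicate block gave 231 for d6 against d4, 10 for d8, and 70 and 42 for those differences. In the first series the block follows depth, and residual correlations within it were 0.228 to 0.32. All human libraries together gave 0 for d8, 13 for the star set minus the first series and 1 for ko against wt iPSCs. Without shallow libraries the counts were 531 for d4 against d2, 10 for d8, 1309 for 585A1 iMeLC, 63 and 38 for those differences. Without day 2 libraries mouse d6 against d4 gave 69. The crossed pairing gave 333 for ko against wt at d2.

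Leaving out each library in turn gave 314 to 564 for iMeLC, 1876 to 2397 for d2, 167 to 380 for d4, 17 to 237 for d6 against d4, 0 to 61 for d8 and 2830 to 3118 for d6 against hiPSC. The ranges were 2308 to 2390 in the star set, 387 to 434 for 585A1 iMeLC, 2294 to 2773 for 585A1 d6, 1 to 57 for the star set minus the first series and 0 to 64 for 585A1 minus 585B1-868. They were 1 to 4, 195 to 320 and 1317 to 1429 for ko against wt iPSCs, d2 and d4, 2913 to 3179 for wt d4 and 898 to 1018 for ko minus wt. In mouse they were 918 to 1149 for EpiLC, 1727 to 2683 for d2, 1721 to 2113 for d6 against EpiLC and 29 to 58 for d6 against d4.

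Of 316 list tests 106 were called, 46 with an estimated correlation and 113 with a replicate block. With the block the lists called of 16 went from 7 to 11 for iMeLC, from 2 to 3 for d6 against d4 and from 7 to 5 for ko against wt at d2. Without shallow libraries they went from 7 to 10 for iMeLC, from 7 to 9 for d2, from 2 to 5 for d4 against d2, from 2 to 5 for d6 against d4 and from 0 to 3 for d8, but there the spread was borrowed from the star set and 585A1, whose replicates agreed better (0.977 to 0.983 against 0.934 to 0.946), so these rises are no evidence of more changes. For ko against wt at d4 the early germ cell list passed with no filter (0.01276), a pseudocount of 10 (0.04013) and all human libraries together (0.03575), the neural list failed with no filter (0.301), and the primitive streak list failed with a filter at 30 (0.18). The median of the cynomolgus early germ cell list, 4.12, was 2.30 with a pseudocount of 10 and 3.56 with a mean of at least 50. Simulated changes of log2 1.5 were recovered in 89.4% of cases for iMeLC, 93.9% for ko against wt at d4 and 63.6% for mouse EpiLC. Of the simulated calls 28 were false for iMeLC (12.8% of 218, over the 5% set), 7 for ko against wt and 6 for EpiLC. Calls of the iMeLC comparison may thus hold more false ones than the threshold states. The other comparisons of the first series share its fit and its deep and shallow replicates. They were not simulated and may hold more false calls too.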

Other observations

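No test in this part was planned, and the comparison across species was chosen only after the results were seen. Changes were set side by side for human day 6 against hiPSC, mouse day 6 against EpiLC, and cyPGC against cyESC, across genes, which are not independent replicates. A gene moved in all 3 species when it was called in human and mouse and changed in cynomolgus by at least 1 on the log2 scale. In cynomolgus the change also had to go the same way at all 3 ages. Of 232 genes that moved in all 3 species, 134 moved the same way, where unrelated directions would give 57.9. Of these 63 were higher, among them PRDM1, TFAP2C, NANOS3, KIT, SOX15, DND1, NANOG and TFCP2L1, and 71 were lower, among them ZIC2, ZIC5, OTX2, DNMT3B and LIN28A. In 50 genes human and cynomolgus moved the same way and mouse the opposite way, where unrelated directions would give 57.6. Human was opposite in 23 genes and cynomolgus in 25, against 58.5 and 58.0. Agreement across all 3 species lowers each of these numbers, so those expectations cannot show whether mouse differed more often than chance gives. Among genes that disagreed, mouse was the opposite one most often, which was not tested. SOX2, PRDM14 and FGFR2 were among the 26 of the 50 mouse-opposite genes lower in human, and DNMT3L and HHEX were among the 24 higher. These examples were chosen after their values were seen.

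Human and cynomolgus changes had a correlation of 0.355 (rank correlation 0.291) over 6016 genes. For these pairs a gene moved in both when its absolute log2 change was at least 1 in each, with no test and no rule on age. Of the 1014 such genes, 74.4% moved the same way, where unrelated directions would give 50.1%. For human and mouse the values were 0.157 (0.124) over 7476 genes and 60.9% of 827 genes. For mouse and cynomolgus they were 0.204 (0.163) over 5167 genes and 65.5% of 683 genes. The starting cells differ between the species, so stage and species are not separated.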
